A study of Caenorhabditis elegans with 30 samples.

How the data were processed

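RNA from whole worms was sequenced in 30 libraries: 18 of naive or butanone-conditioned worms after 2 hours on ice and 12 of untrained worms after a night with or without 15 mM lithium chloride. The deposited values are raw counts per gene for each of the 2 experiments. Per the submitters' processing notes the tools were cutadapt, FastQC, HISAT2, HTSeq and DESeq2, given without versions or order, with genome build ce11. The lithium libraries were made with a directional kit, and the ice libraries from cDNA of 1 of 2 SMART-Seq kits with Nextera XT. Which kit served which ice library, and the strand setting of the counting, are not stated. The values were checked: all were whole numbers, columns had different totals, and every column was matched to its sample by its title.

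The counts of the lithium experiment covered 46904 genes, of which 44017 had a symbol, and those of the ice experiment 46778, of which 43818 had one. Symbols and coordinates were taken from the Ensembl annotation of release 115 for the same assembly. Depth was 10111055 to 27794834 counts per lithium-experiment library and 9873554 to 30054357 per ice-experiment library. Replicates spread far more than counting error, with a lowest chi-square per degree of freedom of 23.3, so precision is given as SD between replicates or as SE of the fit. Of 152 genes named, 42 overlap another protein-coding gene, 40 of them on the opposite strand. Among the larger overlaps are those of cng-1 (715 bases), sod-3 (547), flp-28 (653), rpl-24.2 (684), col-14 (1249), R13H4.2 (1630) and ddx-27 (4567), and dagl-2 shares 660 bases with a gene on its own strand. Reads of near-identical relatives (histones, vitellogenins vit-3 to vit-5, collagens, K08D8.4 with K08D8.5) are uncertain in their assignment.

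Counts were fitted in edgeR 4.0.16 (R 4.3.3, limma 3.58.1, data.table, version 1.17.8) with TMM scaling, the filterByExpr filter on low counts, and the robust quasi-likelihood test, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05, all two-sided. The lithium experiment was 1 fit of 12 libraries in 4 groups (12392 genes, common biological coefficient of variation 0.294). Training on ice was tested in 1 fit of 18 libraries in 6 groups (14864 genes, 0.660). For temperature on ice the naive and conditioned counts of each letter at a temperature were added, which gave 9 sums in 3 groups (15412 genes, 0.645), so that each letter counted once within a group. Letter H labels a sum at 15 C and another in shifted worms. The replicate labels were checked by the correlation of residuals: all 9 naive and conditioned pairs of a letter correlated (r 0.471 to 0.897) and 18 of 18 libraries correlated best with their own partner. Among lithium libraries of the same number r ran from -0.316 to 0.346, with 13 of 18 above 0.1, and 8 of 12 libraries correlated best with one of their own number. The series calls the replicates on ice biological, and nothing states whether they or the lithium replicates came from separately grown cultures. CPM are TMM-scaled, with a prior count of 2 where a logarithm is shown.

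Before the data were examined, 27 gene lists were fixed: desaturases and membrane fluidity, cold survival, heat shock, endoplasmic reticulum and mitochondrial chaperones, DAF-16 targets, innate immunity, detoxification, metal response, osmotic response, inositol and GSK-3, diacylglycerol signalling, olfactory signalling, learning, memory and forgetting, neuropeptides, 3 tissue marker lists (neuron, muscle, intestine), vitellogenins, germline and oocyte, embryo, sperm, cuticle and moulting, beta-oxidation and lipolysis, glycolysis and citrate cycle, mitochondrial genome, ribosomal proteins and histones. Each was tested with camera at a preset correlation of 0.01 and with an estimated correlation, and adjusted over the 27 lists of a comparison. Of 297 list tests 73 were called at the preset correlation and 0 with the estimated one (lowest adjusted p = 0.25). The estimate is taken from the residuals of 9 to 18 samples, and marker genes of a tissue vary together between replicates. Medians are of log2 fold changes of the members that passed the filter. A further 2 lists, 46 nucleolar genes and 59 larval moulting-cycle and matrix genes, share no gene with the lists above or with the named genes. They were written after the first results, were also tested with each library left out, and are used in the closing section, adjusted over 14 tests.

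Genes are named by a rule fixed before the data were examined: the 6 higher and 6 lower genes with the largest log2 fold change among those called, with at least 10 CPM and no overlap between the groups' libraries. To these come up to 3 called members of each list and, always, fat-5, fat-6, fat-7 and paqr-2 for temperature and lithium, gsk-3, ttx-7 and inos-1 for lithium, and odr-1, odr-3, egl-4, tir-1 and crh-1 for training. Other members of a list are named only as part of its count, and genes outside the rule are said to be chosen after their values were seen.

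The fits were tested on simulated data with 200 changed genes at the spread of each fit. Recovered were 27% of 2-fold and 76% of 4-fold changes for lithium at 20 C, 24% and 68% for lithium at 15 C, 10% and 58% for training averaged over temperatures, and 0% of either for 15 C against 20 C on ice. The simulated libraries were drawn independently, without the pairing by letter of the real ones. In the real training fit 32 genes had an unadjusted p under 0.05 where 743 are expected by chance. The percentages for training are thus likely too high for that fit. Alternatives were RLE size factors, DESeq2 1.42.0, no filter on low counts, each replicate left out in turn, the replicate as a block, fits of the compared groups alone, and for temperature on ice naive or conditioned libraries alone and no summing. Added after the data were seen were fits without the libraries of replicate 2, without ribosomal RNA and histone genes, and without letters E and B, E and H, or H. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15. Genes without a symbol, 0.788 to 1.20% of the counts of a lithium-experiment library and 0.424 to 1.84% of an ice-experiment library, stayed in the fits. No library and no sample column was left out.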

Results

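Polyadenylated RNA of whole N2 worms, the standard wild type of Caenorhabditis elegans, was sequenced in 2 experiments of a study of cold, lithium and the forgetting of odour memories. In the lithium experiment (12 libraries) untrained worms spent a night at 15 C or 20 C on agar with 15 mM lithium chloride or on plain NGM agar, with 3 libraries in each of the 4 groups. In the ice experiment (18 libraries) worms were either naive or conditioned with the odorant butanone, and all spent 2 hours on ice before RNA extraction. They had been kept at 20 C, at 15 C overnight, or at 15 C overnight and then at 20 C for 2 hours, with 3 libraries in each of the 6 groups. The total count per library ran from 10111055 to 27794834 in the lithium experiment and from 9873554 to 30054357 in the ice experiment. Rows of ribosomal RNA genes held 1.08 to 28.4% of the counts of a lithium-experiment library and 1.49 to 10.1% of the counts of an ice-experiment library.

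Lithium at 20 C was compared with plain agar at 20 C to ask which transcripts lithium changes in worms that remain cold sensitive. Cuticle and moulting genes were lower in lithium-treated worms: 27 of 32 measured members had a negative log2 fold change, 21 were called lower, and the median was -2.77 (adjusted p = 9.4e-09 at the preset correlation, adjusted p = 0.90 with an estimated one). Among them, the furrow collagen dpy-7 had a log2 fold change of -5.91 (SE 1.17, adjusted p = 0.022) and the moulting gene mlt-8 one of -4.02 (SE 0.78, adjusted p = 0.021). Germline and oocyte genes were higher: 33 of 35 members had a positive value, 15 were called higher, none lower, and the median was 0.80 (adjusted p = 1.6e-13 at the preset correlation, adjusted p = 0.90 with an estimated one). The eggshell proteoglycan gene cpg-2 (chromosome III, 7102092 to 7103990) stood at 2806 ± 135 CPM (counts scaled by the TMM-adjusted library size) with lithium and at 1135 ± 474 without (SD, n = 3 each). The germline RNA-binding protein genes mex-3 and gld-1 had log2 fold changes of 0.96 (SE 0.21, adjusted p = 0.027) and 0.83 (SE 0.19, adjusted p = 0.027).

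Several single genes of fuel metabolism, protein folding and the intestine were called lower with lithium at 20 C. The gluconeogenic carboxykinase gene pck-1 (chromosome III, 62888 to 66260) stood at 43.4 ± 10.9 CPM against 147 ± 8.95 in controls (SD, n = 3 each), a log2 fold change of -1.75 (SE 0.22, adjusted p = 0.0046). The fatty acid oxidation genes acs-2 and acdh-2 had log2 fold changes of -2.01 (SE 0.41, adjusted p = 0.023) and -1.51 (SE 0.25, adjusted p = 0.018), and the desaturase gene fat-3 one of -0.99. Of the glycolysis and citrate cycle list pck-2 fell too (-0.71), while gpd-1 rose (0.83, SE 0.24, adjusted p = 0.042). The list of beta-oxidation and lipolysis genes held 5 lower and 0 higher members of 36 and was not called as a list (adjusted p = 0.087). In the list of endoplasmic reticulum and mitochondrial chaperones 3 of 20 members fell: the BiP-type chaperone gene hsp-3 (-0.67, SE 0.14) and the disulfide isomerase genes pdi-6 (-0.75, SE 0.15) and pdi-2 (-0.91, SE 0.16). Of 23 intestine markers 5 fell, among them the peptide transporter gene pept-1 (-1.17, SE 0.25) and the cathepsin gene cpr-5 (-1.11, SE 0.20). Of 22 neuron markers 2 fell, the touch-neuron tubulin genes mec-12 (-1.26) and mec-7 (-1.42).

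Outside these groups, the aspartyl protease gene asp-12 rose from 83.7 ± 3.55 to 310 ± 69.8 CPM with lithium at 20 C (SD, n = 3 each; log2 fold change 1.89, SE 0.29). The poly(ADP-ribose) glycohydrolase gene parg-2 rose as well (2.06, SE 0.47, adjusted p = 0.027), as did the DAF-16 target dod-24 (2.05, SE 0.45) and the small heat shock gene sip-1 (1.09, SE 0.19). The DAF-16 target sod-3 fell (-2.50, SE 0.51, adjusted p = 0.024). From the list of learning, memory and forgetting genes, the kinase gene akt-1 (0.57, SE 0.12, adjusted p = 0.027) and the heterochromatin gene hpl-2 (0.60, SE 0.15, adjusted p = 0.031) rose and the calcium sensor gene ncs-1 fell (-1.36, SE 0.41, adjusted p = 0.0497), while the list as a whole was not called (adjusted p = 0.44). The inositol monophosphatase gene ttx-7, whose product lithium inhibits, had a log2 fold change of 0.34 (SE 0.21, adjusted p = 0.26), and gsk-3, which codes for the lithium-sensitive kinase, one of -0.03 (SE 0.18, adjusted p = 0.92). The inositol phosphate synthase gene inos-1 had 0.46 (SE 0.17, adjusted p = 0.082), and its rows share 1984 bases with xpf-1 on the opposite strand. No call was made for the desaturase genes fat-5 (-0.27), fat-6 (-0.08) and fat-7 (-0.57) or for the membrane fluidity gene paqr-2 (-0.18). With 1 library left out the values ran from 0.16 to 0.57 for ttx-7, -0.13 to 0.03 for gsk-3, -0.55 to -0.08 for fat-5, -0.18 to 0.02 for fat-6, -0.82 to -0.24 for fat-7 and -0.27 to -0.10 for paqr-2.

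The other genes that the naming rule selected with lithium at 20 C went both ways. Higher were clec-3 (1.64), ZK228.4 (1.44), pud-3 (2.37), gst-12 (1.4), K08D8.5 (1.19), flp-5 (1.18), lea-1 (1.03), spe-41 (0.98), irg-3 (0.97), his-74 (0.92), pal-1 (0.76) and dagl-2 (0.67). Lower were vit-3 (-0.78), pho-1 (-0.88), rege-1 (-1.23), tnt-3 (-1.29), cdr-2 (-1.3), ugt-62 (-1.44), trpa-1 (-1.57), cnc-2 (-1.75), aqp-2 (-2.6), myo-2 (-2.75), cyp-14A1 (-2.91), acdh-8 (-3.13) and hch-1 (-3.76), and, with the largest falls, dpy-2 (-5.32), lpr-3 (-5.43), ptr-25 (-5.57), R09E10.5 (-6.27), cut-2 (-6.49) and F41F3.3 (-7.44) (highest adjusted p of these = 0.044). Without control replicate 2 the values were -1.25 for aqp-2, -1.47 for myo-2, -2.12 for hch-1, -2.92 for lpr-3, -3.32 for ptr-25, -3.54 for cut-2 and -4.69 for F41F3.3. In the other direction, leaving out 1 library took cut-2 as far as -11.7 and F41F3.3 as far as -12.2. Of the called genes named above, mlt-8 (-2.58), fat-3 (-0.62) and gpd-1 (0.55) moved by over 1.5 times too, and pud-3 was 1.55 without lithium replicate 2.

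In the edgeR fit 732 of 12392 genes were called higher and 784 lower with lithium at 20 C. Adjusted over the list alone, 22 cuticle and moulting genes were lower and 23 germline genes higher. At the preset correlation camera called 5 of 27 lists: germline (adjusted p = 1.6e-13), cuticle and moulting (9.4e-09), ribosomal proteins (median 0.24, 5.1e-04), neuron markers (median -0.70, 0.021) and intestine markers (median -0.36, 0.049). None of the 5 was called with an estimated correlation (adjusted p = 0.90 for each). The ribosomal protein list held no gene called higher and 1 called lower, rpl-11.2 (-0.56), and its median was 0.39 without control replicate 1 and 0.14 without lithium replicate 3. Control replicate 2 stood apart, with cuticle genes at a mean of 5.28 log2 CPM against 3.53 and 3.94 in the other controls and germline genes at 7.24 against 8.17 and 8.24. Without it the medians were -2.17 for cuticle, 0.49 for germline, -0.25 for neuron (adjusted p = 0.40) and 0.16 for ribosomal proteins (adjusted p = 0.061). The neuron call also ended without lithium replicate 2 (adjusted p = 0.11), and the intestine call without control replicate 1 (median -0.16), control replicate 3 or lithium replicate 2. Many cuticle genes were near the counting floor under lithium: dpy-7 had 11 counts and cut-3 (log2 fold change -7.83, SE 1.49) had 4 counts over the 3 libraries, so the size of their fitted fold depends on the prior count. The number of called genes rested on single libraries: it was 5 without lithium replicate 2, 32 without lithium replicate 1, 43 without lithium replicate 3, 422 without control replicate 2, 1244 without control replicate 3 and 2855 without control replicate 1. The 5 genes left were dhp-2, T16G1.7, ttr-16, clec-5 and clik-3. A fit of the 6 libraries of 20 C alone called 0 genes (2845 at an unadjusted p under 0.05), and DESeq2 on all 12 libraries called 2542.

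**Figure D1:**
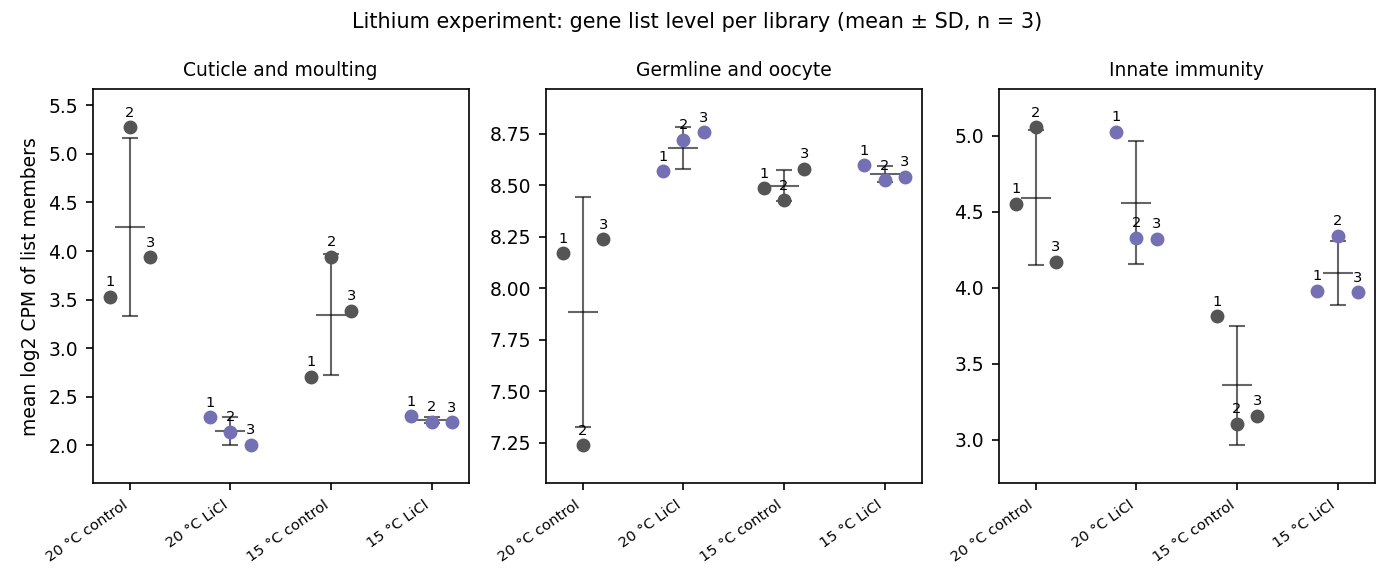
Mean log2 CPM (y axis) of the members of 3 gene lists, cuticle and moulting, germline and oocyte, and innate immunity, in each library of the 4 groups of the lithium experiment (x axis). Points are libraries with their replicate number, and bars give the mean and SD of the 3 libraries. In 20 C controls the cuticle level is 5.28 in replicate 2 against 3.53 and 3.94, and the germline level is 7.24 there against 8.17 and 8.24.

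Lithium at 15 C was compared with plain agar at 15 C to ask what lithium changes in worms that had become cold tolerant. Innate immunity genes were higher: 31 of 36 members had a positive value, with a median of 0.80 (adjusted p = 1.9e-06 at the preset correlation, adjusted p = 0.79 with an estimated one, and a median of 0.47 without lithium replicate 2). Of them 1 passed the test over all genes, the pathogen-response gene K08D8.5 (1.64, SE 0.29, adjusted p = 0.032). Its neighbour K08D8.4, a close relative outside the list, was higher too (2.60, SE 0.43, adjusted p = 0.028). Genes regulated by the FOXO factor DAF-16 had a median of 0.35 (adjusted p = 0.79 with an estimated correlation), and the metallothionein gene mtl-2 among them rose from 67.1 ± 11.2 to 188 ± 53.6 CPM (SD, n = 3 each). The cuticle and moulting list again had a negative median, -1.17, with 24 of 32 members negative and none called (adjusted p = 0.79 with an estimated correlation, and a median of -0.48 without lithium replicate 2).

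Single genes with a clear change at 15 C included parg-2 (chromosome IV, 8712408 to 8715132), at 19.9 ± 1.82 CPM with lithium and 1.3 ± 0.278 without (SD, n = 3 each; log2 fold change 3.94, SE 0.54, adjusted p = 0.0082). The gene clik-3 rose by a log2 fold change of 2.02 (SE 0.16, adjusted p = 0.000189), the lectin gene clec-3 by 2.62 (SE 0.42) and the uncharacterised ZK228.4 by 1.79 (SE 0.25). Among the genes that fell, pck-1 had -1.72 (SE 0.22, adjusted p = 0.0048) and gcn-1, an activator of the amino acid starvation kinase, had -1.55 (SE 0.19, adjusted p = 0.0041), from 215 ± 21 to 73.3 ± 12 CPM. T16G1.7 (-2.40), F42A10.7 (-2.26), txt-14 (-1.88) and clec-5 (-1.48) fell as well. The lithium-target genes were not called: inos-1 had 0.55 (SE 0.17, adjusted p = 0.17), ttx-7 0.27 (SE 0.21, adjusted p = 0.52) and gsk-3 -0.14 (SE 0.18, adjusted p = 0.72). Nor were fat-5 (0.12), fat-6 (0.30), fat-7 (0.03) and paqr-2 (-0.27). With 1 library left out these 4 ran from -0.11 to 0.23, 0.17 to 0.33, -0.26 to 0.30 and -0.43 to -0.08, ttx-7 from 0.18 to 0.34 and gsk-3 from -0.32 to -0.01.

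At 15 C edgeR called 20 genes higher and 28 lower of 12392, and DESeq2 called 433. Adjusted over the list alone, 6 innate immunity genes were higher, and of the DAF-16 targets 5 were higher and 1 lower. Camera called 4 of 27 lists at the preset correlation: innate immunity (adjusted p = 1.9e-06), cuticle and moulting (4.1e-05), DAF-16 targets (0.0072) and muscle markers (median -0.17, 0.0496). None was called with an estimated correlation (adjusted p = 0.79 for the first 3 and 0.85 for muscle). Lithium replicate 2 weighed on these lists: besides the medians given above, that of muscle was 0.0045 without it, and its adjusted p became 1.00. The cuticle median was -0.76 without control replicate 2, the DAF-16 median 0.19 without lithium replicate 1, and the muscle median -0.37 without lithium replicate 1 and -0.47 without lithium replicate 3. The count of genes fell to between 11 and 21 when any 1 library of the comparison was left out, and a fit of the 15 C libraries alone called 264.

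The effects of lithium at both temperatures were compared to see whether they share genes. Across 12392 genes the log2 fold changes correlated with r = 0.585 and rho = 0.467, and genes are not independent replicates. Lithium raised 13 genes at both temperatures (1.18 expected from the product of the counts) and lowered 21 at both (1.77 expected). The contrasts share no library, but both come from 1 fit with 1 estimate of the spread per gene. Genes of low spread are thus called more easily in both, and the product may understate the overlap expected without a shared effect. The numbers of shared genes rested on single libraries: with 1 left out 1 to 13 genes were raised and 4 to 21 lowered at both temperatures (1 and 4 without 20 C lithium replicate 2), and without replicate 2 of every group 3 were raised and 3 lowered. The shared genes included parg-2, clec-3, ZK228.4, K08D8.5 and clik-3 among those raised, and pck-1, gcn-1, clec-5, txt-14, T16G1.7 and F42A10.7 among those lowered. Further shared genes, chosen after their values were seen, were the glutathione transferase gene gst-24 (1.66 at 20 C and 1.33 at 15 C), the dihydropyrimidinase gene dhp-2 (-2.29 and -2.45) and the RNA polymerase III subunit gene rpc-2 (-0.77 and -0.96). With them fell 3 genes for nucleolar and ribosomal RNA processing proteins, nol-58 (-0.76 and -0.91), nath-10 (-0.51 and -0.83) and nsun-1 (-0.98 and -1.3). The rows of nsun-1 overlap a gene on the opposite strand by 2438 bases. When each library was left out in turn, r lay between 0.472 and 0.638.

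**Figure D2:**
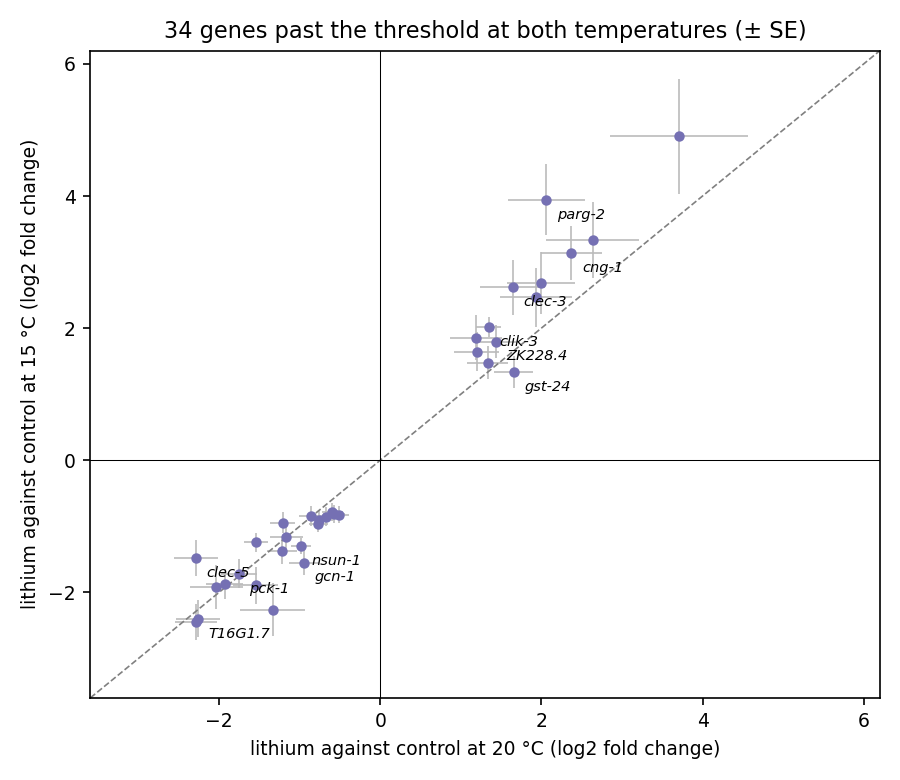
Log2 fold change of lithium against control at 20 C (x axis) and at 15 C (y axis) for the 34 genes called in the same direction at both temperatures. Each point is a gene with its standard errors, and all lie where both values have the same sign, such as clec-5 (-2.29 and -1.48) and parg-2 (2.06 and 3.94). The dashed line marks equal values.

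Whether lithium acted differently at 15 C and 20 C was tested with the interaction of lithium and temperature. Germline and oocyte genes had a lower lithium effect at 15 C than at 20 C: 34 of 35 members had a negative difference, with a median of -0.69 (adjusted p = 9.5e-18 at the preset correlation, adjusted p = 0.68 with an estimated one). Cuticle and moulting genes had a median difference of 1.36 with 30 of 32 members positive (0.44 without 20 C control replicate 2), and innate immunity genes one of 0.59 with 29 of 36 positive (adjusted p = 0.68 with an estimated correlation for both). No gene passed in edgeR (0 of 12392, with 1261 at an unadjusted p under 0.05). DESeq2 called 2, both outside the naming rule and chosen after their values were seen: the nuclear receptor gene nhr-55 (1.49, SE 0.33) and W03D8.8 (1.88, SE 0.40). Of 27 lists 10 were called at the preset correlation and none with an estimated one. The genes named beforehand were far from the threshold, with fat-7 at 0.60, fat-5 at 0.39, fat-6 at 0.38, inos-1 at 0.09, ttx-7 at -0.07, paqr-2 at -0.10 and gsk-3 at -0.11 (lowest adjusted p = 0.51). With 1 library left out fat-7 ran from 0.21 to 0.87, fat-5 from 0.21 to 0.68 and fat-6 from 0.25 to 0.47, and the other 4 changed sign.

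Untrained control worms at 15 C were compared with those at 20 C to describe the night in the cold without training, lithium or ice. Lists of defence, fat breakdown and neuropeptide genes had negative medians at 15 C, and their calls at the preset correlation were lost with an estimated one (adjusted p = 0.25 for innate immunity, beta-oxidation and DAF-16 targets, adjusted p = 0.64 for neuropeptides). Of 36 innate immunity genes 34 had a negative value and 13 were called lower, with a median of -1.22, such as the lysozyme genes lys-1 (-1.21, SE 0.21) and lys-2 (-1.87, SE 0.32). Of 36 beta-oxidation and lipolysis genes 16 fell, with a median of -0.81, such as the peroxisomal genes daf-22 (-1.06, SE 0.20) and maoc-1 (-1.09, SE 0.18). Of 45 neuropeptide genes 8 fell, with a median of -0.75 (-0.47 without 20 C control replicate 2), and flp-6 among them had -1.71 (SE 0.32, adjusted p = 0.027). DAF-16 targets had a median of -1.3 (-0.84 without that library) with 10 of 23 lower, for example the catalase gene ctl-2 (-1.3, SE 0.21) and the metallothionein gene mtl-1 (-3.18, SE 0.70).

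The desaturase genes did not move as 1 group at 15 C. The desaturase gene fat-2 (chromosome IV, 13323873 to 13326395) stood at 535 ± 31.9 CPM against 1226 ± 162 at 20 C (SD, n = 3 each; log2 fold change -1.2, SE 0.17, adjusted p = 0.016), and fat-1 (-0.90) and fat-3 (-1.06) fell as well. For the stearoyl-CoA desaturase genes the values were 0.73 for fat-7 (SE 0.37, adjusted p = 0.15), 0.62 for fat-5 (SE 0.25, adjusted p = 0.096) and -0.07 for fat-6, and paqr-2 had -0.12. With 1 library left out fat-7 ran from 0.47 to 1.09, fat-6 from -0.15 to 0.03 and paqr-2 from -0.20 to -0.04. The intestinal protease gene cpr-4 fell from 1313 ± 439 to 321 ± 74.9 CPM, and the unfolded protein response factor gene xbp-1 fell by 1.13 on the log2 scale (SE 0.23). Higher at 15 C were rbm-3.1, a relative of cold-inducible RNA-binding protein genes (1.04, SE 0.26), and the nucleolar protein genes nucl-1 (0.99, SE 0.23) and snu-13 (1.00, SE 0.21). Ribosomal protein genes had a median of 0.38 with 75 of 77 positive and 4 called higher, rpl-9, rpl-21, rpl-24.2 and rpl-25.2 (adjusted p = 0.64 with an estimated correlation). Germline genes had a median of 0.59 (adjusted p = 0.51 with an estimated correlation, and a median of 0.32 without 20 C control replicate 2) with 1 called, daz-1 (0.71, SE 0.20). The histone list had a median of 0.90 (adjusted p = 0.65 with an estimated correlation), yet both members that passed the test, his-37 (-1.06) and the variant gene his-71 (-1.22), were lower, and histone levels moved with the share of ribosomal RNA across the 12 libraries. The lithium-target genes gsk-3 (-0.29), inos-1 (-0.37) and ttx-7 (-0.01, from -0.19 to 0.22 with 1 library left out) were not called.

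The other genes that the naming rule selected in untrained worms at 15 C were these. Higher were F42A10.7 (2.05), R03D7.2 (1.52), K09H9.7 (1.0), spe-41 (0.92) and hpl-2 (0.64). Lower were aldo-2 (-0.53), crt-1 (-0.65), osm-11 (-0.66), pdi-6 (-0.74), nlp-7 (-0.83), pry-1 (-0.89), flp-28 (-0.89), cpr-1 (-0.9), ets-4 (-0.91), pck-2 (-0.98), pqm-1 (-1.11), flp-22 (-1.16), ctl-1 (-1.35), plc-2 (-1.41), lfe-2 (-1.43), hsp-12.3 (-1.44), unc-64 (-1.5), nas-37 (-1.55), spp-2 (-1.8), smf-3 (-1.82), ftn-1 (-1.86), cyp-33C8 (-2.46), cyp-34A9 (-2.65), col-14 (-2.68), lipl-2 (-2.83), qua-1 (-2.94) and cyp-14A1 (-3.07), and, with the largest falls, T26H5.9 (-3.8), F33H12.7 (-3.87), tts-1 (-3.94), C49G7.7 (-4.0), F53B2.8 (-4.6) and cut-3 (-4.83) (highest adjusted p of these = 0.0497). Without 20 C control replicate 2 the values were -1.13 for T26H5.9, -2.40 for F33H12.7, -2.51 for tts-1, -2.64 for C49G7.7, -2.76 for F53B2.8, -2.49 for cut-3, -1.17 for qua-1, -1.55 for cyp-34A9, -0.67 for nas-37, -0.98 for unc-64, -0.84 for hsp-12.3, -0.94 for lfe-2 and -0.80 for plc-2. Of the called genes named above, his-71 (-0.64) and fat-3 (-0.69) moved by over 1.5 times too.

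In edgeR 272 genes were higher and 963 lower at 15 C of 12392, and DESeq2 called 3048. Adjusted over the list alone, 28 innate immunity, 19 beta-oxidation, 16 DAF-16 target and 13 neuropeptide genes were lower. Camera called 14 of 27 lists at the preset correlation. Besides innate immunity (adjusted p = 6.0e-10), ribosomal proteins (3.3e-11), germline (5.7e-09), neuropeptides and beta-oxidation (7.4e-06 each), DAF-16 targets (1.6e-05) and histones (0.014), these were intestine (median -0.55), metal response (-0.64), cold survival (-0.68), osmotic response (-0.65), cuticle (-1.53), neuron (-0.69) and muscle (-0.46). With an estimated correlation none was called, and the adjusted p ran from 0.25, for 7 lists including innate immunity, to 0.81 for muscle. The count was 0 without 15 C control replicate 2 or 3, 199 without 15 C control replicate 1, 69 without 20 C control replicate 2, and 2418 or 2828 without either of the other 20 C controls. Ribosomal RNA genes held 28.4% and 24.2% of the counts of 15 C control replicates 2 and 3. Their share was 1.3% in 15 C control replicate 1 and at most 8.14% in the 20 C controls. The 15 C controls also serve as controls of the lithium comparison at 15 C. A fit of the 6 control libraries alone called 0 (3530 at an unadjusted p under 0.05). Without 20 C control replicate 2 the medians were -0.37 for cuticle (adjusted p = 0.054), -0.25 for neuron (0.26) and -0.20 for muscle (0.70). Muscle was also not called without 20 C control replicate 3 (0.15) or 15 C control replicate 1 (0.064), nor cuticle without 15 C control replicate 1 (0.14), nor histones without 20 C control replicate 3 (0.12). These 20 C controls are also the controls of the lithium comparison at 20 C.

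On ice, worms kept at 15 C were compared with worms kept at 20 C to ask what marks cold tolerance. Neuron markers had a median log2 fold change of 1.32 at 15 C with 21 of 24 members positive, cuticle and moulting genes one of 1.38 with 43 of 47 positive, and learning, memory and forgetting genes one of 0.89 with 31 of 35 positive. Histone genes had a median of -1.39, ribosomal protein genes one of -0.92 and germline genes one of -0.50 with 32 of 35 negative. These 6 lists were called at the preset correlation and lost with an estimated one (adjusted p = 0.67 each). The desaturase genes had positive values that did not pass: fat-6 stood at 431 ± 353 CPM at 15 C and 141 ± 28.9 at 20 C (SD over 3 letters; log2 fold change 1.61, SE 0.74, adjusted p = 0.39), fat-5 had 1.04 (SE 0.46), fat-7 0.64 (SE 0.83) and paqr-2 0.35 (SE 0.44). With 1 letter left out fat-6 ran from 0.78 to 2.06, fat-7 from -0.20 to 1.06 and paqr-2 from 0.06 to 0.62. No gene passed in edgeR (0 of 15412, 1945 at an unadjusted p under 0.05), while DESeq2 called 160. The median over all genes was 0.14 with TMM and 0.03 with RLE size factors, so list medians also depend on the scaling.

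Camera called 12 of 27 lists for 15 C against 20 C on ice at the preset correlation: the 6 above (histones adjusted p = 6.2e-13, ribosomal proteins 5.0e-10, germline 2.2e-06, cuticle 9.4e-05, neuron 0.00024, memory 0.0018), muscle (median 0.88), sperm (0.76), neuropeptides (0.77), olfactory signalling (1.19), embryo (-0.47) and mitochondrial genome (-0.59). With an estimated correlation none was called (adjusted p = 0.80 for neuropeptides, adjusted p = 0.67 for the others). Letter E of 20 C carried the ribosomal protein value: its libraries averaged 10.0 to 10.3 log2 CPM for this list against 7.78 to 8.54 in the other 16, and without it the median was 0.20 (adjusted p = 0.84). Letter B of 15 C had the highest neuron marker levels, 2.51 and 2.62, and without it the medians were 0.85 for neuron, 0.46 for memory and -0.22 for germline genes. The histone median was -0.37 without letter E, and the germline median -1.14 without G and -0.31 without H. Sperm genes had 0.25 without G, 0.39 without F and 2.52 without E, and neuropeptides 0.25 without B or H, 0.31 without A, 0.49 without F, 1.23 without G and 1.31 without E. Without B olfactory signalling had 0.33, muscle 0.41 and embryo genes -0.26. Embryo genes had -0.08 without E, -0.72 without A and -0.74 without G, and the mitochondrial genome had -0.11 without E. Leaving out a letter ended further calls: embryo and muscle without B, mitochondrial genome without G or E, sperm without G, A or F, olfactory signalling without B, H or A, neuropeptides without B, H, A or F.

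**Figure D3:**
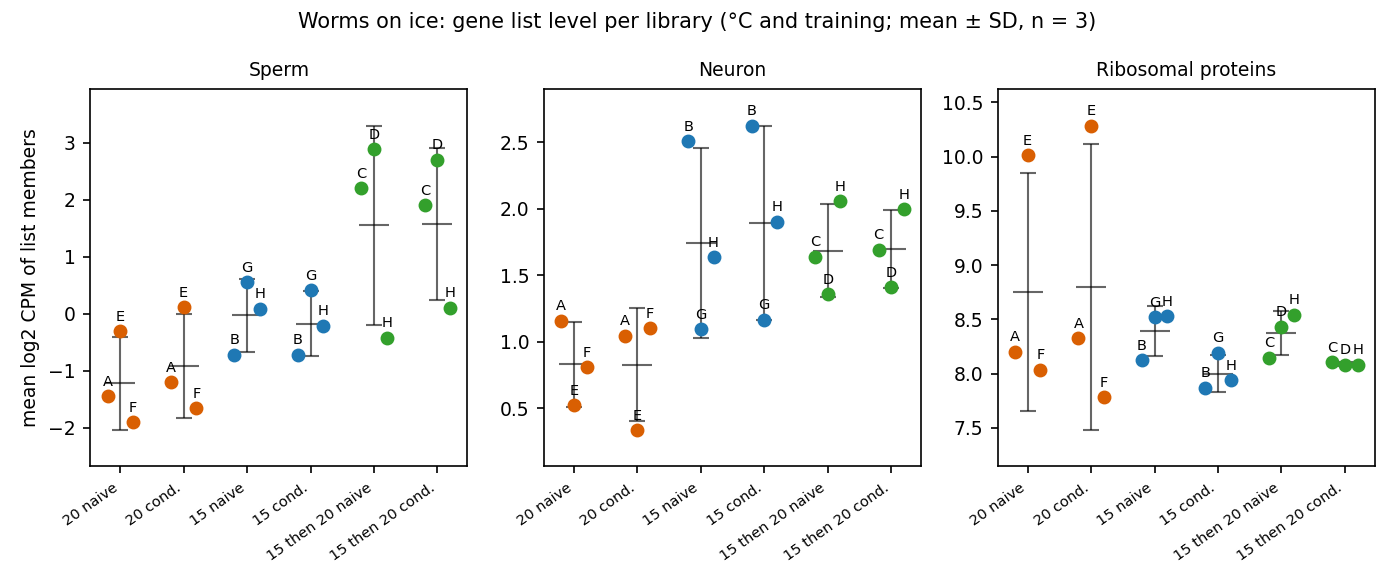
Mean log2 CPM (y axis) of the members of 3 gene lists, sperm, neuron markers and ribosomal proteins, in each library of the 6 groups on ice (x axis). Points are libraries with their letter, and bars give the mean and SD of the 3 libraries. Letter E of 20 C lies highest for ribosomal proteins (10.0 and 10.3), letter B of 15 C for neuron markers (2.51 and 2.62), and letter D for sperm genes (2.70 and 2.89).

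Worms moved from 15 C to 20 C for 2 hours were compared with worms left at 15 C, to ask what a return to 20 C reverses. Sperm genes were the 1 list called: 24 of 27 members had a positive value with a median of 2.72 (adjusted p = 4.5e-20 at the preset correlation, adjusted p = 0.64 with an estimated one). Their level differed by letter, at 1.91 to 2.20 mean log2 CPM in letter C, 2.70 to 2.89 in letter D and -0.42 to 0.11 in letter H, which also labels libraries of 15 C. Without letter C, D or H of the shifted worms, or any letter of 15 C, the median stayed between 1.95 and 3.20 and was called each time. The values of fat-7 (1.47, SE 0.84), fat-5 (0.74, SE 0.46), paqr-2 (-0.15) and fat-6 (-0.21) did not pass (adjusted p = 1.00 each). With 1 letter left out these 4 ran from 0.98 to 2.3, 0.46 to 0.98, -0.41 to 0.11 and -0.996 to 0.62. No gene passed in edgeR (0 of 15412, 512 at an unadjusted p under 0.05, 771 expected by chance). DESeq2 called 1, the sulfurtransferase gene mpst-4 (5.39, SE 1.04), chosen after its value was seen.

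The same shifted worms were compared with worms kept at 20 C throughout, to ask what the night at 15 C left behind after 2 hours. These groups share no letter. Sperm genes had a median of 3.28 with 26 of 27 members positive, and 11 were higher adjusted over the list alone. The same list had a median of 2.72 against worms left at 15 C and of 0.76 in 15 C against 20 C (from 0.25 to 2.52 with 1 letter left out). Its level also differed by letter within the shifted worms. A remainder of the night at 15 C thus cannot be told apart from differences between letters. Cuticle genes had a median of 1.36, with 7 of 47 higher adjusted over the list alone, and neuron markers one of 1.2. Histone (-1.38), ribosomal protein (-0.94) and germline (-0.48) genes had negative medians. These 6 lists were called at the preset correlation and lost with an estimated one (adjusted p = 0.70 for sperm and cuticle, adjusted p = 0.73 for the others). The desaturase gene fat-5 stood at 22.4 ± 1.5 CPM against 6.50 ± 2.48 (SD over 3 letters; log2 fold change 1.78, SE 0.47, adjusted p = 0.12), fat-7 had 2.11 (SE 0.86, adjusted p = 0.37), fat-6 1.4 (SE 0.74) and paqr-2 0.19 (SE 0.44). With 1 letter left out fat-6 ran from 0.62 to 1.66 and paqr-2 from -0.10 to 0.46.

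No gene passed for shifted worms against 20 C in edgeR (0 of 15412, 1855 at an unadjusted p under 0.05), while DESeq2 called 873. Without letter H of the shifted worms 554 genes passed. Within the fit of single libraries the naive worms alone and the conditioned worms alone each gave the 3 genes R11D1.3, cnp-2 and F41H10.1, chosen after their values were seen. Camera called 12 of 27 lists: sperm (adjusted p = 1.0e-13), histones (9.6e-10), ribosomal proteins (8.9e-09), cuticle (1.0e-06), germline (2.0e-05), neuron (0.0038), neuropeptides (median 0.99), muscle (0.69), embryo (-0.59), mitochondrial genome (-0.38), vitellogenins (-1.39) and innate immunity (-0.24). With an estimated correlation none was called, and the last 6 had an adjusted p of 0.73. Without letter E the ribosomal protein median was 0.16 (adjusted p = 0.78) and the mitochondrial one 0.10 (0.67), the histone median was -0.47 and the sperm median 5.24, and embryo was not called. Without letter H the germline, neuron, muscle, embryo, neuropeptide, mitochondrial and vitellogenin lists were not called, and the medians were 0.05 for neuropeptides, 0.37 for muscle, -0.25 for germline and -1.31 for innate immunity. Innate immunity had -0.06 without C, -0.09 without D, -0.03 without E and -0.41 without F, and the mitochondrial genome -0.69 without C, -0.08 without D and -0.66 without F. Without C muscle had 0.45, germline -0.78, embryo -0.93 and vitellogenins -2.42, and embryo had -0.22 without E. Without A the vitellogenin (median 0.06), neuropeptide and innate immunity lists were lost. The vitellogenin call also ended without D or F, the innate immunity call without C or D, the neuropeptide call without F and the mitochondrial call without D.

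**Figure D4:**
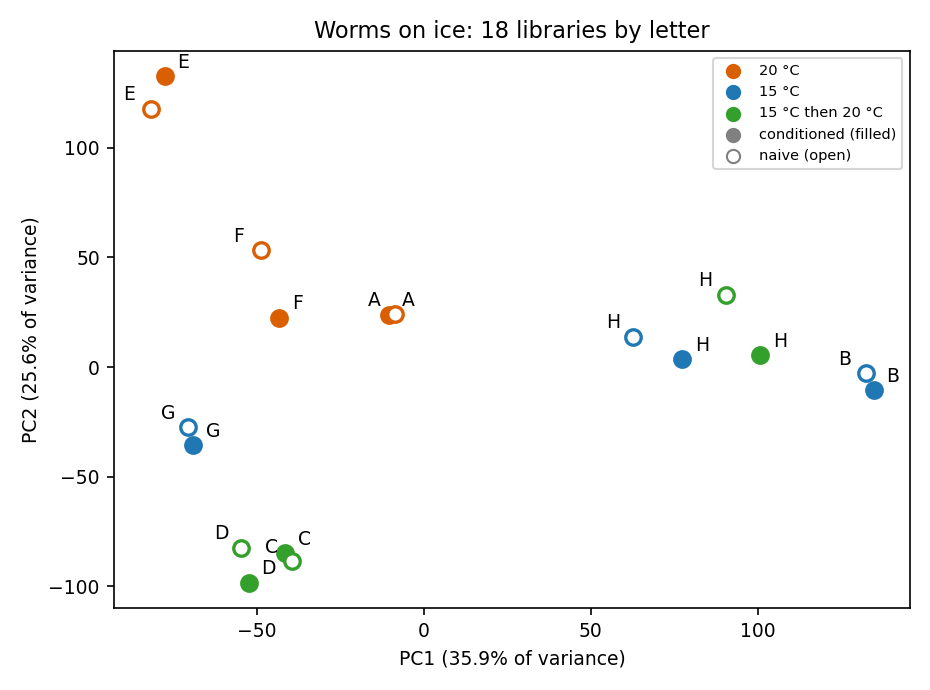
First (x axis) and second (y axis) principal component of log2 CPM of the 18 libraries on ice, which hold 35.9% and 25.6% of the variance. Each point is a library with its letter. The naive and conditioned library of letter B of 15 C lie close together, at 132 and 135 on the first component. Those of letter F of 20 C lie further apart, at 53.4 and 22.5 on the second.

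Genes called in the untrained temperature comparison were followed on ice, in libraries of the other experiment. Of the 272 genes higher at 15 C in untrained worms 271 were measured on ice, and their median at 15 C against 20 C was -0.12, while other genes had 0.15 (adjusted p = 9.9e-05). In shifted worms their median was -0.07 against 15 C (adjusted p = 0.49) and -0.18 against 20 C (adjusted p = 9.9e-05). Of the 963 lower genes 957 were measured, with medians of 0.41 for 15 C against 20 C (adjusted p = 0.49), -0.24 for shifted worms against 15 C (adjusted p = 0.0025) and 0.18 against 20 C (adjusted p = 0.44). With an estimated correlation the adjusted p was 0.92 for all 6. The first median changed sign without letter B (0.08) or H (0.0090) of 15 C, and the -0.18 without letter H of the shifted worms (0.02). The -0.24 changed sign without letter B of 15 C (0.09) or letter C (0.11) or D (0.06) of the shifted worms, and without H of 15 C its adjusted p was 0.82.

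Conditioned worms were compared with naive worms to ask which transcripts follow butanone training, averaged over the 3 cultivation groups. Ribosomal protein genes had a median of -0.18 in this average, with all 78 negative, while the medians of the groups were 0.18 at 20 C, -0.40 at 15 C and -0.30 in shifted worms. Neuropeptide genes had a median of -0.14 with 31 of 47 negative. The ribosomal protein list had an adjusted p of 8.1e-11 and the neuropeptide list one of 8.5e-04, and with an estimated correlation adjusted p = 0.94 for both. Of the forgetting and odour genes named beforehand, the guanylyl cyclase gene odr-1 had a log2 fold change of 0.81 (SE 0.64, from 0.39 to 2.33 with 1 library left out), the TIR-domain gene tir-1, which promotes forgetting, 0.10 (SE 0.72), the kinase gene egl-4 0.09 (SE 0.29) and the CREB gene crh-1 -0.18 (SE 0.41). None passed (adjusted p = 1.00 each), and the G protein gene odr-3 was below the count filter. No gene passed in edgeR (0 of 14864) or in DESeq2 (0). In the edgeR fit, which does not use the pairing of the letters, 32 genes had an unadjusted p under 0.05 where 743 are expected by chance, and with the letter as a block 1151 did and 0 passed. With the letter as a block, ribosomal proteins had a median of -0.21 (adjusted p = 1.2e-25), and vitellogenins (-0.13, adjusted p = 0.038) and the mitochondrial genome (-0.18, adjusted p = 0.0056) were called too. List tests with the block, here and within each cultivation group, were run at the preset correlation only. For training no list was tested with a library left out, so how far single libraries carry these calls is not known. Without the block no list was called with an estimated correlation. The blocked medians of 20 C, 15 C and shifted worms, in this order, were 0.07, -0.40 and -0.29 for ribosomal proteins, -0.12, -0.25 and -0.02 for vitellogenins, and -0.07, 0.18 and -0.60 for the mitochondrial genome.

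Within each cultivation group training differences were again called in gene lists alone, and these lists were not tested with single libraries left out. At 20 C histone genes had a median of 0.59 (adjusted p = 0.011, adjusted p = 0.98 with an estimated correlation), which was 0.22 with the letter as a block, where innate immunity was called too (0.16, adjusted p = 0.045). At 15 C ribosomal proteins had a median of -0.40 with 77 of 78 negative (adjusted p = 1.3e-19), neuropeptides -0.18, innate immunity -0.30, histones -0.22, intestine markers -0.19, glycolysis -0.13 and embryo genes 0.20, and all 7 calls were lost with an estimated correlation (adjusted p = 1.00). With the letter as a block, at the preset correlation only, the embryo call was lost (0.27, adjusted p = 0.093) while heat shock genes (-0.10, adjusted p = 0.044) and vitellogenins (-0.25, adjusted p = 0.012) were added. In shifted worms ribosomal proteins had -0.30 with 78 of 78 negative (adjusted p = 1.4e-10), the mitochondrial genome -0.39, neuropeptides -0.18, histones -0.19 and innate immunity -0.13. All 5 were called with the block as well, at the preset correlation. Without the block all 5 were lost with an estimated correlation (adjusted p = 0.99).

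The forgetting genes did not pass in any cultivation group. For odr-1 the values were 1.81 at 20 C (from 0.55 to 6.36 with 1 library left out), 0.24 at 15 C and 0.37 in shifted worms, for tir-1 0.17, -0.04 and 0.17, for egl-4 0.14, 0.04 and 0.08, and for crh-1 0.04, -0.41 and -0.17. With 1 library left out tir-1, egl-4 and crh-1 changed sign in every group and in the average, and odr-1 at 15 C and in shifted worms. In edgeR 0 genes passed at 20 C (60 at an unadjusted p under 0.05), 0 at 15 C (17) and 0 in shifted worms (7), where 743 are expected by chance in each, and DESeq2 called 0 in each. With the letter as a block 0 passed and 547, 584 and 460 had such a p. The interaction of training and temperature called 0 genes in edgeR (12 at an unadjusted p under 0.05, 262 with the letter as a block) and 0 in DESeq2.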

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

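The lists below were fixed before the data were examined, while the tests of single libraries and of tissue share were chosen after the result was seen. In 10 of 27 lists the lithium effect differed between 15 C and 20 C by a test of the interaction at the preset correlation, and none of them was called with an estimated one (adjusted p = 0.68 to 0.99). Germline and oocyte genes had a median difference of -0.69 (adjusted p = 9.5e-18), innate immunity genes 0.59 (adjusted p = 0.00024) and intestine markers 0.50 (adjusted p = 0.00042). Mitochondrial genome genes had 0.59 (12 of 12 positive, adjusted p = 0.00078), cuticle and moulting genes 1.36 (adjusted p = 0.00080), beta-oxidation and lipolysis genes 0.52 (adjusted p = 0.0079) and metal response genes 0.57 (adjusted p = 0.013). Smaller differences were those of glycolysis genes (-0.11), ribosomal proteins (-0.060) and histones (-0.48), each with an adjusted p of 0.028. With an estimated correlation the adjusted p was 0.68 for the first 7, 0.99 for glycolysis and ribosomal proteins and 0.90 for histones. When each of the 12 libraries was left out in turn, 6 lists were called every time, metal response 10 times, glycolysis 9 times, and ribosomal proteins and histones 6 times each. The medians ran from -0.21 to 0.030 for glycolysis and from -0.21 to 0.030 for ribosomal proteins, so both changed sign, from -1.02 to -0.31 for histones and from 0.30 to 0.79 for metal response. Without 20 C control replicate 2 the cuticle difference was 0.44 and the beta-oxidation difference 0.22, and without 15 C lithium replicate 2 the mitochondrial difference was 0.28.

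The pattern weighed here is the low level of cuticle and moulting genes with lithium at 20 C. A single control library as the sole source is argued against: the list median was still -2.17 without control replicate 2. A smaller germline share in the control worms, which would raise every somatic tissue alike, is argued against as the sole source. The cuticle median lay -2.33 from that of neuron, muscle and intestine markers (permutation p = 1e-05, the smallest the resampling can give). That permutation shuffled genes, which are not independent replicates, so its p does not measure the spread between libraries. These markers had a median of -0.44 themselves, so a part played by germline share is not excluded. Larvae among the control worms remain open as a candidate explanation. A separate list of 59 larval moulting-cycle and matrix genes was written after the cuticle result and before its own values were seen. Its median was -1.3, with 39 of 41 measured members lower and 15 called. The adjusted p was 4.1e-08 at the preset correlation and 0.39 with an estimated one, and the median was -0.74 without control replicate 2. With lithium at 15 C the list had a median of -0.48 with 28 of 41 lower (adjusted p = 0.00078, adjusted p = 0.47 with an estimated correlation). Its genes are of the same kind as the cuticle and moulting list, so its drop cannot tell larvae from lower expression of such genes in adults. A direct effect of lithium on cuticle gene expression in adults, which the design names, was not tested and stays open.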

How the results depend on the processing

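The replicate as a block left most counts near the unblocked ones: 1479 genes for lithium at 20 C (1284 shared with the fit without it), 63 for lithium at 15 C (43 shared), 1252 for untrained temperature (1021 shared) and 0 for lithium by temperature, for training in every group and for training by temperature. With the block, training averaged over temperatures had 1151 genes at an unadjusted p under 0.05. The block reversed crh-1 in training at 20 C (-0.062) and egl-4 in training of shifted worms (-0.0059), and with it the 2 lithium effects correlated at r = 0.572. No paired analysis was possible for temperature on ice because the cultivation groups have different letters, apart from H.

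With RLE size factors the counts were 1515, 60 and 1208 for lithium at 20 C, lithium at 15 C and untrained temperature, and 0 elsewhere. DESeq2 called 2542, 433 and 3048 for these, 2 for lithium by temperature, and on ice 160 for 15 C against 20 C, 1 for shifted worms against 15 C and 873 for shifted worms against 20 C. Without a filter on low counts the numbers were 972, 284 and 1320 for the temperature comparisons on ice in that order, 984 for lithium at 20 C and 711 for untrained temperature. Training then had 1 gene averaged over temperatures, 2 at 20 C, 2 at 15 C and 3 in the interaction with temperature. No summing per letter gave 48 genes for 15 C against 20 C on ice and 1143 for shifted worms against 20 C. That setting counts the correlated naive and conditioned libraries of a letter as separate replicates, so its counts overstate the replication. Shifted worms against 20 C had 3 with naive libraries only, 3 with conditioned libraries only and 411 with letters E and H left out, where paqr-2 reversed to -0.094. With only the groups compared in the fit, lithium at 20 C had 0, lithium at 15 C 264 and untrained temperature 0. Without replicate 2 of every group these had 13, 9 and 0, and the lithium effects correlated at r = 0.5175. Without ribosomal RNA and histone genes lithium at 15 C had 73. The cause of these differences was not tested.

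Named genes were followed through 2480 alternative values of 187 genes in comparisons: 1630 stayed the same, 775 were weaker, 5 stronger and 70 reversed. For lithium at 15 C fat-7 (0.03) reversed with RLE size factors (-0.0047), DESeq2 (-0.0046), only the groups compared (-0.025) and no ribosomal RNA or histone genes (-0.030). Without replicate 2 of every group gsk-3 was 0.11 at 20 C and 0.086 at 15 C, and inos-1 by temperature was -0.11. In untrained temperature ttx-7 was 0.0081 with RLE and with DESeq2.

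When each library or sum was left out in turn, counts stayed at 0 to 0 for 15 C against 20 C on ice, for shifted worms against 15 C, for all training comparisons and for lithium by temperature. They ran from 0 to 554 for shifted worms against 20 C, 5 to 2855 for lithium at 20 C, 11 to 21 for lithium at 15 C and 0 to 2828 for untrained temperature. Signs changed on ice for fat-7 in 15 C against 20 C (-0.20 to 1.06), paqr-2 (-0.41 to 0.11) and fat-6 (-0.996 to 0.62) in shifted worms against 15 C, and paqr-2 against 20 C (-0.10 to 0.46). In training averaged over temperatures they changed for tir-1 (-0.41 to 0.68), egl-4 (-0.023 to 0.22) and crh-1 (-0.52 to 0.079). At 20 C they changed for tir-1 (-0.77 to 1.31), egl-4 (-0.10 to 0.54) and crh-1 (-0.97 to 0.77). At 15 C the ranges were -0.13 to 0.91 for odr-1, -0.20 to 0.33 for egl-4, -1.64 to 1.62 for tir-1 and -1.17 to 0.34 for crh-1. In shifted worms they were -0.086 to 0.77 for odr-1, -1.07 to 1.45 for tir-1, -0.26 to 0.44 for egl-4 and -0.41 to 0.074 for crh-1. With lithium the ranges were -0.13 to 0.031 for gsk-3 and -0.18 to 0.024 for fat-6 at 20 C, and -0.11 to 0.23 for fat-5 and -0.26 to 0.30 for fat-7 at 15 C. In lithium by temperature they were -0.056 to 0.18 for inos-1, -0.30 to 0.12 for ttx-7, -0.22 to 0.082 for paqr-2 and -0.26 to 0.0094 for gsk-3, and in untrained temperature -0.19 to 0.22 for ttx-7 and -0.15 to 0.029 for fat-6. The correlation of the lithium effects ran from 0.472 to 0.638.

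For genes higher at 15 C in untrained worms the medians on ice ran from -0.50 to 0.082 (15 C against 20 C), -0.26 to 0.28 (shifted against 15 C) and -0.39 to 0.021 (shifted against 20 C) when a sum was left out. For genes lower at 15 C they ran from 0.12 to 0.74, -0.998 to 0.11 and -0.51 to 0.35. With an estimated correlation 3 calls ended, at -0.12 and -0.18 for the higher genes against 20 C and -0.24 for the lower genes in shifted worms against 15 C (adjusted p = 0.92). Lists with an absolute log2 fold change of at least 1 gave 0.10 and -0.0065 for the higher genes against 20 C (adjusted p = 0.37), and lists made without 20 C control replicate 2 gave -0.065 for the lower genes in shifted worms against 15 C (adjusted p = 0.59).

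Following the temperature genes of ice under lithium had been planned and could not be run, since 15 C against 20 C on ice called 0 genes. In its place stood genes with an unadjusted p under 0.01, chosen after the data were seen. Under lithium at 20 C the 102 measured higher genes had a median of -0.96 (adjusted p = 3.6e-06) and the 38 lower genes one of -0.43 (adjusted p = 0.043), and neither was called with an estimated correlation (adjusted p = 0.58). Under lithium at 15 C they had -0.090 (adjusted p = 0.055) and 0.12 (adjusted p = 0.63), and neither was called. Of the 73 gene lists called at the preset correlation 0 were called with an estimated one.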

Other observations

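Of the tests in this part, those of letter E, 20 C control replicate 2, larval share and conditioning behind the opposite lists and of single libraries behind the nucleolar and larval lists, those of ribosomal RNA with histones, and the regroupings of every comparison other than lithium at 20 C, lithium at 15 C and untrained temperature were chosen after the result was seen. Genes for nucleolar and ribosome assembly proteins were higher at 15 C in untrained control worms: in a separate list 43 of 46 had a positive log2 fold change, 17 were called higher and the median was 0.50 (adjusted p = 7.7e-12 at the preset correlation, adjusted p = 0.39 with an estimated one). This direction had not been predicted, and nucl-1 and snu-13, which are not on the list, had been seen higher before. On ice the list showed no such rise at 15 C against 20 C. Its median there was 0.024 with 24 members higher and 22 lower (adjusted p = 0.145). It was -0.29 without letter G and 0.20 without letter H of 15 C. The list was written to test whether lithium may lower such genes, after nol-58, nath-10 and nsun-1 had been seen lower. At 15 C 33 of 46 were lower with lithium, with a median of -0.25 (adjusted p = 4.1e-08, adjusted p = 0.39 with an estimated correlation). At 20 C the median was -0.13 (adjusted p = 0.39), so the prediction of a drop at both temperatures was not met, and the question stays open.

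In 7 lists the temperature difference was called in both experiments, and in 7 of 7 its sign was opposite. At 15 C neuropeptide genes had a median of -0.75 in untrained worms and 0.77 on ice, neuron markers -0.69 and 1.32, muscle markers -0.46 and 0.88, and cuticle genes -1.53 and 1.38. Germline genes had 0.59 and -0.50, ribosomal proteins 0.38 and -0.92, and histones 0.90 and -1.39. All of these calls are at the preset correlation, and none holds with an estimated one. The 7 lists need not be separate results: neuropeptide, neuron, muscle and cuticle genes went one way and germline, ribosomal protein and histone genes the other. A different germline share among the worms was not tested for this pattern and stays open. Histone levels in the lithium experiment also moved with the share of ribosomal RNA (r = 0.922), so their untrained value may not reflect temperature. Letter E of 20 C fits as the source for ribosomal proteins, whose median on ice was 0.20 without it and no longer opposite. For the other 6 lists letter E as the sole source is argued against: 6 of 6 kept their sign and call without it, though the histone median was -0.37. The neuropeptide call on ice held in 2 of 6 fits with a sum left out. For neuron, muscle and cuticle genes 20 C control replicate 2 cannot be ruled out as the source, since 0 of 3 kept their call in untrained worms without it (medians -0.25, -0.20 and -0.37). For the other 4 lists, neuropeptides, germline, ribosomal proteins and histones, 4 of 4 kept sign and call. The genes lower in untrained worms at 15 C decide nothing about either source: their median on ice was 0.57 without letter E, with no call against other genes (adjusted p = 1.00), and 0.0047 with lists made without 20 C control replicate 2. Different shares of larvae among the worms stay open: the larval list had a median of 1.65 at 15 C on ice (adjusted p = 5.5e-05, lowest 0.89 without letter B) and of -1.19 in untrained worms (adjusted p = 0.022), with adjusted p = 0.47 and 0.60 at an estimated correlation. The untrained value rests on 20 C control replicate 2, without which it was -0.31 (adjusted p = 0.22). Genes of the larval list are of the same kind as the cuticle list, so it cannot tell larvae from expression in adults. Conditioning with butanone as the source is argued against: in naive worms alone 7 of 7 lists kept the opposite sign on ice and their call at the preset correlation (highest adjusted p = 0.0023), with medians of 0.84 for neuropeptides, 1.12 for neuron, 0.86 for muscle, 1.17 for cuticle, -0.46 for germline, -0.64 for ribosomal protein and -1.07 for histone genes. Ice and kit differ between the experiments and cannot be separated from this, nor can a difference of day, which is not stated.

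Histone transcripts, most of which lack a poly(A) tail, moved with ribosomal RNA in the lithium experiment. Over 12 libraries the log2 share of ribosomal RNA and the mean histone level had r = 0.922 (permutation p = 0.00017) and rho = 0.825 (permutation p = 0.0018). Without the 2 libraries farthest from the median r was 0.819, and within groups it was 0.938. Carry-over of RNA without poly(A) tails may explain this. Cultivation at 15 C as the sole source is argued against by 3 libraries at 15 C that had a lower ribosomal RNA share than the highest at 20 C. Yet the highest shares, 28.4, 24.2 and 13.8%, were all at 15 C, against at most 8.14% at 20 C. In this order they belong to control replicates 2 and 3 and lithium replicate 2. A contribution of 15 C is thus not excluded.

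Whether lithium and 15 C move the same genes was asked of the main effects across 12392 genes. Their correlation was 0.183, larger in size than in 31 of 99 regroupings of the 12 libraries (highest 0.784), and it was -0.03 without 20 C control replicate 2. The prediction that it would exceed nearly all regroupings was not met. Because regroupings alone reach such high values, the test cannot exclude a shared response, and the question stays open.

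Other splits of the same libraries were fitted for each comparison. A comparison of 3 against 3 has 10 splits, too few for a share under 0.05, so these give the real value and the highest other. Lithium at 20 C called 1516 genes and no other split any (1 of 10 splits reached the real count). Lithium at 15 C called 48 and the highest other 4, and untrained 15 C against 20 C called 1235 and the others 0. For temperature on ice the real count was 0 each time, which all 10 splits reach by necessity, and the highest other was 0 for 15 C against 20 C and for shifted worms against 20 C. For shifted worms against 15 C a split called 2529 genes: letters B and H of 15 C with H of the shifted worms against G, C and D, which points to a structure by letter. For training the real count was 0 at 20 C, 15 C and in shifted worms, and at 20 C a split of both A libraries and conditioned F against both E libraries and naive F called 779. The highest other was 0 at 15 C and in shifted worms, and it was 0 in all groups among the 4 splits that part each letter's pair, as the real one does. For training averaged over temperatures, training by temperature and lithium by temperature the real count was 0 as well, which all 100 of 100 drawn regroupings reach by necessity, so these regroupings decide nothing. The highest other was 0, 1725 and 63 in that order, and the 1725 points to a structure of the samples.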
